A study of Homo sapiens with 16 samples.

How the data were processed

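RNA was sequenced from the cell lines Cal33 and SAS grown in a laminin-rich matrix gel after transfection with siControl or an ITGA7 siRNA pool, with 4 libraries in each of 4 groups. Per the labels' protocols, ribosomal RNA was depleted, strand-specific libraries were made and paired-end reads were sequenced. Per the submitters' processing notes, GSNAP 2020-12-16 and featureCounts 2.0.1 were used with the GRCh38 build; the notes give no roles, and the annotation release and the strand setting are not given in the sources used here. Antisense and overlapping genes are therefore uncertain, and so are genes with near-identical copies. Processed pseudogenes took 3.89% to 5.69% of the counts per library, and genes such as the ribosomal proteins may share reads with them, which was not tested.

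The authors deposited 3 tables of the same libraries. The first holds raw read counts per gene, whole numbers with no normalization, for 31966 genes with at least 1 read. The second holds what the deposited values show to be those counts divided by 1 size factor per library, a normalised signal rounded by the authors. With the factor estimated from the deposited values themselves, the raw counts over it differed from them by at most 0.176 normalised counts. These factors ran from 0.691 to 1.535, and median-of-ratios factors computed from the raw counts from 0.66 to 1.465. The third holds the authors' regularised log values, which are log2 values per the file name, and a deposited column of the GC percent of each gene. All tests used the raw counts; the normalised counts served as a check of the scaling. The log2 table was used for the GC percent and was compared with the computed log2 CPM (Spearman correlation across genes 0.994 to 0.995 per library; genes are not independent replicates). No per-sample column was left unused in the mapping (0 columns).

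Counts were fitted with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr over the groups, which left 21086, library sizes were scaled by TMM, and 1 model with a mean per group was fitted to all 16 libraries, so that the groups share an estimate of the spread. The quasi-likelihood F test gave the p-values, adjusted by Benjamini-Hochberg, with an adjusted p under 0.05 as the threshold and an absolute log2 fold change of at least 1 as a second count. The SE of a fold change is its size over the square root of F. The comparisons were siITGA7 against siControl in each line, the difference between these effects, and SAS against Cal33 in siControl.

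The design, the alternatives, the rule for named genes and 42 gene lists were fixed before the data were examined. Of the lists 40 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01; camera with an estimated correlation and fry were run beside it. By fry, which tests whether a list's genes move on balance one way, 11 lists passed in Cal33, 15 in SAS, 13 for the difference and 35 between the lines. No list called by camera had a median or mean of the other sign than its test; among lists not called, the median and the test differed in sign for 7 in Cal33, 7 in SAS, 6 for the difference and 2 between the lines, and the mean differed from the median in sign for some. The lists of fibroblast and endothelial markers had 2 and 4 tested members and were not tested. Some lists share genes, so their calls are not independent. For example, NT5E and TGFB2 are in the EMT and YAP/TAZ lists. PFKFB3 is in the hypoxia and glycolysis lists, and VLDLR in the hypoxia and unfolded protein response lists. The genes named are ITGA7; in each line and direction the 6 largest fold changes and 5 further genes of smallest p among genes past the threshold with an average log2 CPM of at least 1, a gene symbol and no overlap between the 4 and 4 libraries; 6 per direction for both lines; 5 per direction for the difference; 5 per direction between the lines at an average log2 CPM of at least 3; and members of lists among the 4 of smallest p. Which of these list members to name, mostly the first and second, and the naming of integrins, a list that was not called, were chosen after their values were seen. Some genes that the rule names are not reported here and were not replaced. The labels call the libraries biological replicates without describing how cultures were separated, so p-values measure the spread between these libraries.

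Total counts ranged from 20052929 to 43803871 per library. No replicate pair agreed within sampling noise (chi-square per gene 4.68 or more), so each library counted once. On simulated counts with the real means and depths, the test recovered 49.3% of 67 genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of 66 changed 4-fold in Cal33, among 20781 genes, with 4.73% false calls. In SAS it recovered 52.2%, 88.1% and 97.0% among 20792 genes, with 8.14% false calls. Changes were given only to genes above a minimum mean CPM. The simulated counts held no GC trend and no library that stands apart, so these rates cover neither those nor rarer genes. Intervals and floors of 3 counts cover counting error only.

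The labels give the replicate number as a batch, 1 of 4, shared by the groups, so the numbers pair the libraries by label. The check of the data gave correlations between deviations of same-numbered siControl and siITGA7 libraries of -0.123 to 0.0221 in Cal33 and -0.179 to 0.119 in SAS. The fit with the replicate number as a block within each line is printed beside results it changes.

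Alternatives planned were RLE and total-count scaling, DESeq2 1.42.0, limma-voom, no filter or CPM above 1 in 4 libraries, fits of the compared libraries alone, both replicate blocks, a test against a fold of 1.2, and leaving out each library in turn. Chosen after seeing the data were removal of each library's GC trend (lowess, span 0.3), the same with the replicate block or without replicate 1 of Cal33 siITGA7, the replicate block without the Cal33 libraries numbered 1, and protein-coding genes alone. Other splits of the libraries were refitted, 35 for each comparison of 8 libraries and 60 drawn for the difference between lines. For genes shared by the lines, each of the 60 was also given as many genes per line and direction as the real split calls, taken by p, a test chosen after seeing the data.

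For the search of siRNA seed matches, the 3′ UTRs of 13383 protein-coding genes were taken from GENCODE v29 by gene identifier (length of at least 30 bases). The search was run in 1 form, with Cal33 fold changes from the fit without replicate 1 of siITGA7. The log2 fold change was regressed on the presence of each of 16205 words of 7 bases found in at least 50 genes, with UTR length, UTR GC, gene GC and expression level as covariates, each with its square, and with extreme fold changes clipped, in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. With fold changes shuffled over genes, for each line by itself, 0 words were called in both lines. Such shuffling removes correlation between genes and between lines, so it does not give the rate of false words on the real fold changes. The regression itself counts genes as independent. A made-up word with a log2 effect of 0.3 in 301 genes ranked first. That effect was larger than any found for the words called in both lines, so recovery at their size was not tested. Figures were drawn with matplotlib 3.10.9.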

Results

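Gene expression was measured by RNA sequencing in 2 human cell lines derived from head and neck squamous cell carcinoma without papillomavirus, Cal33 and SAS. The cells were grown inside a laminin-rich matrix gel (Matrigel), which surrounds them with basement-membrane proteins instead of a plastic surface. In each line, cells received either a pool of siRNAs against ITGA7, which encodes the α7 subunit of a laminin-binding integrin, or a non-targeting control pool (siControl). Each of the 4 groups (Cal33 siControl, Cal33 siITGA7, SAS siControl and SAS siITGA7) held 4 libraries that the labels call biological replicates, so 16 libraries were compared. The total count per library ranged from 20052929 to 43803871 reads assigned to genes, and 21086 of the 31966 listed genes had enough counts to be tested. Levels are group means in CPM (counts scaled to library size), with the SD over the 4 libraries after ± where it is given. Fold changes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with their standard error (SE) on the log2 scale.

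The first question was whether the siRNA pool lowered its target. ITGA7 (ENSG00000135424, minus strand of chromosome 12, 55684568 to 55716043, GRCh38) was a low-abundance transcript in both lines. In Cal33 it fell from 5.55 ± 1.17 CPM (SD, n = 4) in siControl to 2.49 ± 0.587 CPM (SD, n = 4) in siITGA7, which was 55.1% lower. In SAS it fell from 1.85 ± 0.432 CPM (SD, n = 4) to 0.756 ± 0.168 CPM (SD, n = 4), which was 59.2% lower. The log2 fold change was -1.17 (SE 0.202, edgeR adjusted p = 0.00106) in Cal33 and -1.27 (SE 0.256, edgeR adjusted p = 0.00189) in SAS. Every siITGA7 library lay below every siControl library of its line: the highest siITGA7 value was 3.03 CPM against a lowest siControl value of 4.23 CPM in Cal33, and 0.977 against 1.45 CPM in SAS. These levels rest on 13 to 232 counts per library. The effect on ITGA7 did not differ detectably between the lines (difference of log2 fold changes -0.11, SE 0.321, adjusted p = 0.872).

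**Figure D1:**
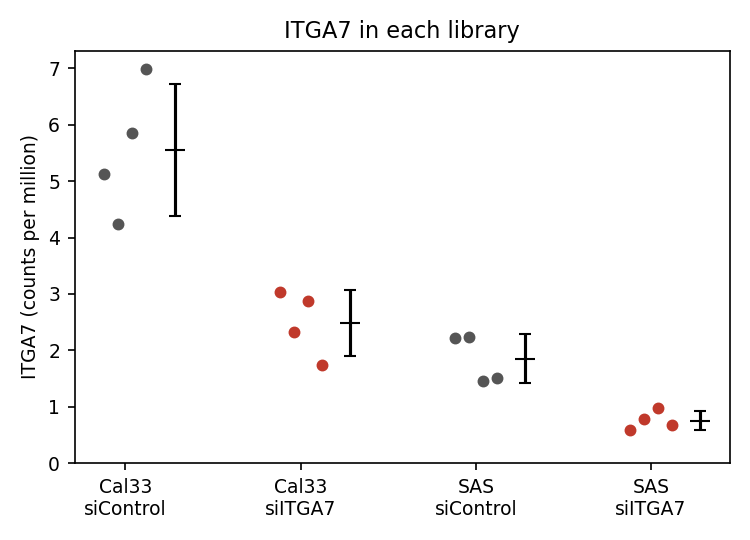
ITGA7 in CPM (vertical axis) in the 4 libraries of each group (points), with the group mean and SD beside them (bar and whiskers). All siITGA7 libraries lie below the siControl libraries of their line, at most at 3.03 CPM in Cal33 and 0.977 CPM in SAS.

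The next comparison asked which transcripts changed in Cal33 when ITGA7 was silenced. CCN1 (chromosome 1, 85580761 to 85584589, GRCh38), a matricellular protein and a standard target of the YAP and TAZ co-activators, rose from 52.2 ± 3.08 to 144 ± 11.8 CPM (SD, n = 4 each). The WNT antagonist DKK1 rose from 11.5 ± 0.976 to 32.2 ± 3.75 CPM, and the neutrophil chemokine CXCL8 from 4.60 ± 0.832 to 16.3 ± 1.95 CPM (SD, n = 4 each). The transcription factor CREB5 had the largest rise among the genes named for Cal33, 4.62-fold (0.892 ± 0.192 to 4.10 ± 0.821 CPM). The sphingosine kinase SPHK1 rose 3.93-fold, the small GTPase RRAD 3.95-fold and the tetraspanin TSPAN2 3.56-fold. The keratins KRT86 and KRT80 rose 3.09-fold and 2.84-fold, IFFO2 2.72-fold, and F3, the tissue factor that starts coagulation, 2.14-fold.

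Genes that fell in Cal33 included the adenylate kinase AK4, from 202 ± 12.5 to 89.7 ± 5.72 CPM, and the mitotic kinase AURKA, from 120 ± 3.25 to 55.8 ± 3.26 CPM (SD, n = 4 each). The phospholipid scramblase PLSCR4 fell 3.28-fold, the lipoprotein lipase inhibitor ANGPTL4 3.21-fold, the MAP kinase kinase MAP2K6 3.16-fold, the ribonuclease ANG 2.68-fold, the receptor GPR160 2.66-fold and the histone-binding chaperone NPM3 2.45-fold. The ubiquitin-conjugating enzyme UBE2Q2 fell 2.22-fold, the elongation factor ELL2 2.19-fold and the nucleotide-synthesis enzyme PRPS2 2.00-fold. For all of these, the 4 siITGA7 libraries lay on one side of the 4 siControl libraries, which the rule for named genes required.

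Several of the gene lists fixed in advance moved up in Cal33. Of 33 measured genes of MAPK feedback and EGFR ligands, 14 rose and 1 fell, including the phosphatase DUSP6 (log2 fold change 1.05, SE 0.0841) and the EGFR ligand AREG (0.86, SE 0.0788), with a camera adjusted p of 7.22e-12. YAP/TAZ targets rose at 10 of 26 genes and fell at 2, including CCN1 and F3 (camera adjusted p = 2.2e-08). Heat shock and chaperone genes rose at 12 of 23 with none lower, including HSPB8 (0.85, SE 0.127) and HSPH1 (0.71, SE 0.126; camera adjusted p = 1.42e-08). Mesenchymal and EMT genes rose at 7 of 29 and fell at 1, with the ectonucleotidase NT5E at 0.90 (SE 0.104) and the myosin light chain MYL9 at 1.60 (SE 0.205; camera adjusted p = 0.00722). NF-kB targets and inflammatory cytokines rose at 11 of 32 and fell at 1, with the ubiquitin-editing enzyme TNFAIP3 at 0.77 (SE 0.091); the camera adjusted p was 7e-07, and the adjusted p was 0.172 with an estimated correlation.

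The hypoxia list went down in Cal33. Of its 30 measured genes 13 fell and none rose, including AK4 and the prolyl hydroxylase EGLN3 (log2 fold change -0.77, SE 0.131), with a median of -0.33 (camera adjusted p = 4.05e-09; adjusted p = 0.276 with an estimated correlation). NRF2 and oxidative stress genes fell at 8 of 33 and rose at 1, among them NFE2L2 itself (-0.54, SE 0.0933) and the glutathione-synthesis subunit GCLM (-0.44, SE 0.0858; camera adjusted p = 0.0124; adjusted p = 0.494 with an estimated correlation). The mean of this list over siControl was -0.44 on the log2 scale in replicate 1 of siITGA7 and -0.09 to -0.08 in the other 3. Without that library the call ended (camera adjusted p = 0.116) and the median was -0.06 instead of -0.14. Matrix proteases and inhibitors rose at 7 of 29 and fell at 2, with ADAMTS1 at 0.82 (SE 0.112) and ADAM19 at 0.72 (SE 0.1; camera adjusted p = 0.0124; adjusted p = 0.135 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose at 9 of 33 and fell at 4, with HMGCS1 at 0.90 (SE 0.117) and SQLE at 0.47 (SE 0.0714; camera adjusted p = 0.0141; adjusted p = 0.276 with an estimated correlation). The call ended without siControl replicate 4 (camera adjusted p = 0.0611). AP-1 and immediate early genes rose at 5 of 28 and fell at 1, with KLF6 at 0.76 (SE 0.0952) and JUN at 0.91 (SE 0.117); that list was called at a camera adjusted p of 0.0408, which became 0.0654 with the replicate number as a block, and the adjusted p was 0.844 with an estimated correlation. The call of AP-1 and immediate early genes also ended without siControl replicate 2 or siITGA7 replicate 2 or 3 (camera adjusted p = 0.16, 0.268 and 0.0748), with limma-voom (0.094), with a CPM filter (0.0558), in the 8 Cal33 libraries alone (0.0715), in protein-coding genes (0.0746) and with the GC trend removed (0.251).

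Replication-dependent histones and cytosolic ribosomal proteins were also called lower as lists in Cal33, although only 2 of 35 histone genes (H2BC7 at -0.64, SE 0.143, and H2AC6 at -0.49, SE 0.147) and 1 of 52 ribosomal protein genes (RPL14 at -0.91, SE 0.104) passed the test singly. Their camera adjusted p was 0.000146 and 0.0124, and the adjusted p was 0.73 and 0.784 with an estimated correlation. Both lists were lowest in replicate 1 of siITGA7: their mean over siControl was -1.11 and -0.43 on the log2 scale there, against -0.17 to -0.15 and -0.08 to -0.05 in the other 3. Without that library the median of replication-dependent histones was -0.20 instead of -0.43 (camera adjusted p = 0.00246). The call of the cytosolic ribosomal proteins ended (camera adjusted p = 0.0983), with a median of -0.03 instead of -0.09. With siControl replicate 1 left out as well and the replicate block, the histone call ended too (camera adjusted p = 0.0587). H2AC6 in Cal33 was at -0.31 without replicate 1 of siITGA7. Its call ended with the replicate block (edgeR adjusted p = 0.0842). It also ended without siControl replicate 1, 2, 3 or 4 (log2 fold change -0.42, -0.52, -0.52 or -0.50) and without SAS siITGA7 replicate 3 (-0.49). Replicate 1 of Cal33 siITGA7 also differed from the other libraries of its group in that 0.98% of its counts came from mitochondrially encoded genes against 2.19% to 2.91% in the other 3, and its correlation with them was at most 0.976. MALAT1 took 1.63% of its counts against 0.723% to 0.906% in the other 3. The labels give it an RNA concentration of 28.8 ng per µl, the lowest of the 16 libraries, against 36.3 to 41.6 in the other 3, and the same RNA integrity number of 10. Among integrin subunits other than ITGA7, 4 of 19 rose and 1 fell, with ITGB1, the partner of the α7 subunit, at 0.45 (SE 0.116) and ITGA4 at -0.79 (SE 0.204), and the list was not called (camera adjusted p = 0.58). ITGB1 in Cal33 was at 0.28 without replicate 1 of siITGA7 and at 0.40 without siControl replicate 4, which ended its call (edgeR adjusted p = 0.053). The call for ITGA4 in Cal33 ended without siControl replicate 3 (-0.74, edgeR adjusted p = 0.055) or siITGA7 replicate 4 (-0.67, edgeR adjusted p = 0.0581).

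Adjusted over the list alone, the counts of higher and lower genes in Cal33 were 17 and 1 for MAPK feedback, 11 and 4 for YAP/TAZ, 17 and 0 for heat shock, 9 and 1 for EMT, 13 and 2 for NF-kB, and 0 and 16 for hypoxia. They were 2 and 10 for NRF2, 7 and 2 for matrix proteases, 10 and 4 for cholesterol synthesis, 6 and 2 for AP-1, 0 and 1 for histones, 0 and 1 for ribosomal proteins, and 4 and 1 for integrins. The lists not called included p53 targets (7 of 30 higher and 3 lower, camera adjusted p = 0.0766), G2/M and mitosis (4 of 41 lower, camera adjusted p = 0.0554) and focal adhesion (3 of 36 higher and 2 lower, camera adjusted p = 0.65).

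In total 2334 genes differed in Cal33 by edgeR's quasi-likelihood test at an adjusted p under 0.05, 1272 higher and 1062 lower, and 252 of them had an absolute log2 fold change of at least 1. With the replicate number as a block within each line the count was 1214, and fitting the 8 Cal33 libraries alone gave 1316. Leaving out siControl replicate 2 or 3 gave 1553 or 1305 genes. Of the 40 lists tested, 12 were called, 8 higher and 4 lower, and 4 of the 12 held with an estimated correlation (MAPK feedback, heat shock, YAP/TAZ and EMT).

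The same question was asked in SAS. GBP4 (chromosome 1, 89181144 to 89198942), an interferon-inducible GTPase, rose 6.10-fold, from 1.48 ± 0.30 to 8.90 ± 1.36 CPM (SD, n = 4 each). ANGPTL4 rose 4.99-fold, the neuronal enolase ENO2 3.57-fold, the lipoprotein receptor VLDLR 3.14-fold, the ubiquitin ligase HERC3 3.02-fold and DEPP1 3.00-fold. The receptor for platelet-activating factor PTAFR rose 2.59-fold, the actin-binding protein MTSS1 2.29-fold, the urokinase PLAU 2.13-fold, the peptide-trimming protease ERAP1 2.07-fold (49.3 to 102 CPM), and the kinase MAST4 1.88-fold.

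CCDC86 (chromosome 11, 60842113 to 60851081) had the largest fall among the genes named for SAS, 4.95-fold, from 74.7 ± 4.23 to 15.1 ± 1.78 CPM (SD, n = 4 each). CCND1, which encodes the G1 cyclin D1, fell from 609 to 245 CPM (2.48-fold). AURKA fell 2.94-fold, NPM3 3.00-fold, the dehydrogenase DHRS2 3.75-fold, the deiodinase DIO2 3.35-fold and RAP1GAP2 2.59-fold. MAT2B, a subunit of the enzyme that makes S-adenosylmethionine, fell 2.42-fold, the mitofusin MFN2 1.99-fold and the focal adhesion protein vinculin (VCL) 1.97-fold.

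Hypoxia genes moved up in SAS: 24 of 30 rose and 1 fell, with a median log2 fold change of 0.56 (camera adjusted p = 2.92e-18; adjusted p = 0.092 with an estimated correlation). NDRG1 was at 1.47 (SE 0.17), and the single gene that fell was AK4 (-1.05, SE 0.0796). Glycolysis genes rose at 10 of 23 with none lower, including ENO2 and the glucose transporter SLC2A3 (1.23, SE 0.168; camera adjusted p = 1.91e-05; adjusted p = 0.303 with an estimated correlation). Epithelial junction genes rose at 15 of 37 and fell at 3, with E-cadherin (CDH1) at 0.66 (SE 0.0726) and CLDN4 at 1.33 (SE 0.146; camera adjusted p = 3.69e-07). Matrix proteases and inhibitors rose at 10 of 29 and fell at 1, including PLAU and the membrane-type protease MMP14 (0.85, SE 0.0974; camera adjusted p = 5.63e-05). Antigen presentation genes rose at 9 of 22 with none lower, including ERAP1 and the MHC light chain B2M (0.57, SE 0.0783; camera adjusted p = 1.04e-06; adjusted p = 0.0568 with an estimated correlation). Interferon-stimulated genes rose at 11 of 42 with none lower, with DDX60 at 0.69 (SE 0.106) and STAT2 at 0.44 (SE 0.0757; camera adjusted p = 0.00298; adjusted p = 0.0941 with an estimated correlation).

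Laminins and basement membrane genes rose at 7 of 23 and fell at 1 in SAS; the laminin chain LAMC1 was at 0.52 (SE 0.0698) and the gene that fell was SPARC (-0.71, SE 0.0932; camera adjusted p = 0.00598; adjusted p = 0.418 with an estimated correlation). YAP/TAZ targets moved down, with 10 of 26 lower and 1 higher, including CCN2 (-1.13, SE 0.171) and AJUBA (-0.63, SE 0.0864; camera adjusted p = 0.00134; adjusted p = 0.113 with an estimated correlation). Heat shock and chaperone genes fell at 6 of 23 with none higher, with DNAJB1 at -0.41 (SE 0.0783) and CCT5 at -0.41 (SE 0.097; camera adjusted p = 0.00298; adjusted p = 0.203 with an estimated correlation). Unfolded protein response and ATF4 targets fell at 10 of 31 and rose at 2, with the amino acid transporter SLC7A5 at -1.34 (SE 0.128) and VLDLR among those that rose (camera adjusted p = 0.0104; adjusted p = 0.0847 with an estimated correlation). AP-1 and immediate early genes fell at 8 of 28, with SRF at -0.44 (SE 0.0905) and MAFK at -0.52 (SE 0.124; camera adjusted p = 0.047; adjusted p = 0.732 with an estimated correlation). The AP-1 and immediate early genes lost their call in SAS without siControl replicate 1 or 2, siITGA7 replicate 1 or 4, or Cal33 siITGA7 replicate 1 (camera adjusted p = 0.0588 to 0.226). They also lost it with a CPM filter (0.0978), in the 8 SAS libraries alone (0.0994), in protein-coding genes (0.156) and with the GC trend removed (0.0596). The call of unfolded protein response and ATF4 targets ended in protein-coding genes (0.0792). Replication-dependent histones fell at 5 of 35, with H4C4 at -0.44 (SE 0.111) and H1-1 at -0.46 (SE 0.118; camera adjusted p = 0.00187; adjusted p = 0.628 with an estimated correlation). Among integrin subunits 5 of 19 rose, with ITGA5 at 0.79 (SE 0.174) and ITGB6 at 0.88 (SE 0.212), and the list was not called (camera adjusted p = 0.173). The call for H4C4 in SAS ended without siControl replicate 3 (-0.35, edgeR adjusted p = 0.0504), and that for ITGB6 in SAS with limma-voom (0.86, adjusted p = 0.0561).

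Adjusted over the list alone, the counts of higher and lower genes in SAS were 27 and 2 for hypoxia, 12 and 1 for glycolysis, 18 and 3 for epithelial junctions, 13 and 4 for matrix proteases, 10 and 0 for antigen presentation, and 11 and 0 for interferon-stimulated genes. They were 7 and 1 for laminins, 3 and 12 for YAP/TAZ, 0 and 9 for heat shock, 3 and 10 for the unfolded protein response, 0 and 10 for AP-1, 0 and 7 for histones, and 6 and 1 for integrins. Focal adhesion genes, which include VCL, were not called as a list (5 of 36 higher and 6 lower, camera adjusted p = 0.861), and their median (0.05) and mean (-0.05) had different signs.

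In SAS 3311 genes differed by edgeR's quasi-likelihood test, 1477 higher and 1834 lower, and 351 of them had an absolute log2 fold change of at least 1. The count was 2128 with the replicate number as a block, and 5236 when replicate 1 of Cal33 siITGA7, which shares in the estimate of the spread, was left out. Of the 40 lists, 12 were called, 7 higher and 5 lower, and 2 held with an estimated correlation (epithelial junctions and matrix proteases). With the block, mitochondrially encoded genes were also called higher in SAS (camera adjusted p = 0.0412, against 0.0701 without it; adjusted p = 0.732 with an estimated correlation and no block), with 0 of 13 members past the edgeR test. They took 3.46% to 4.85% of the counts in siITGA7 against 2.48% to 3.73% in siControl.

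**Figure D2:**
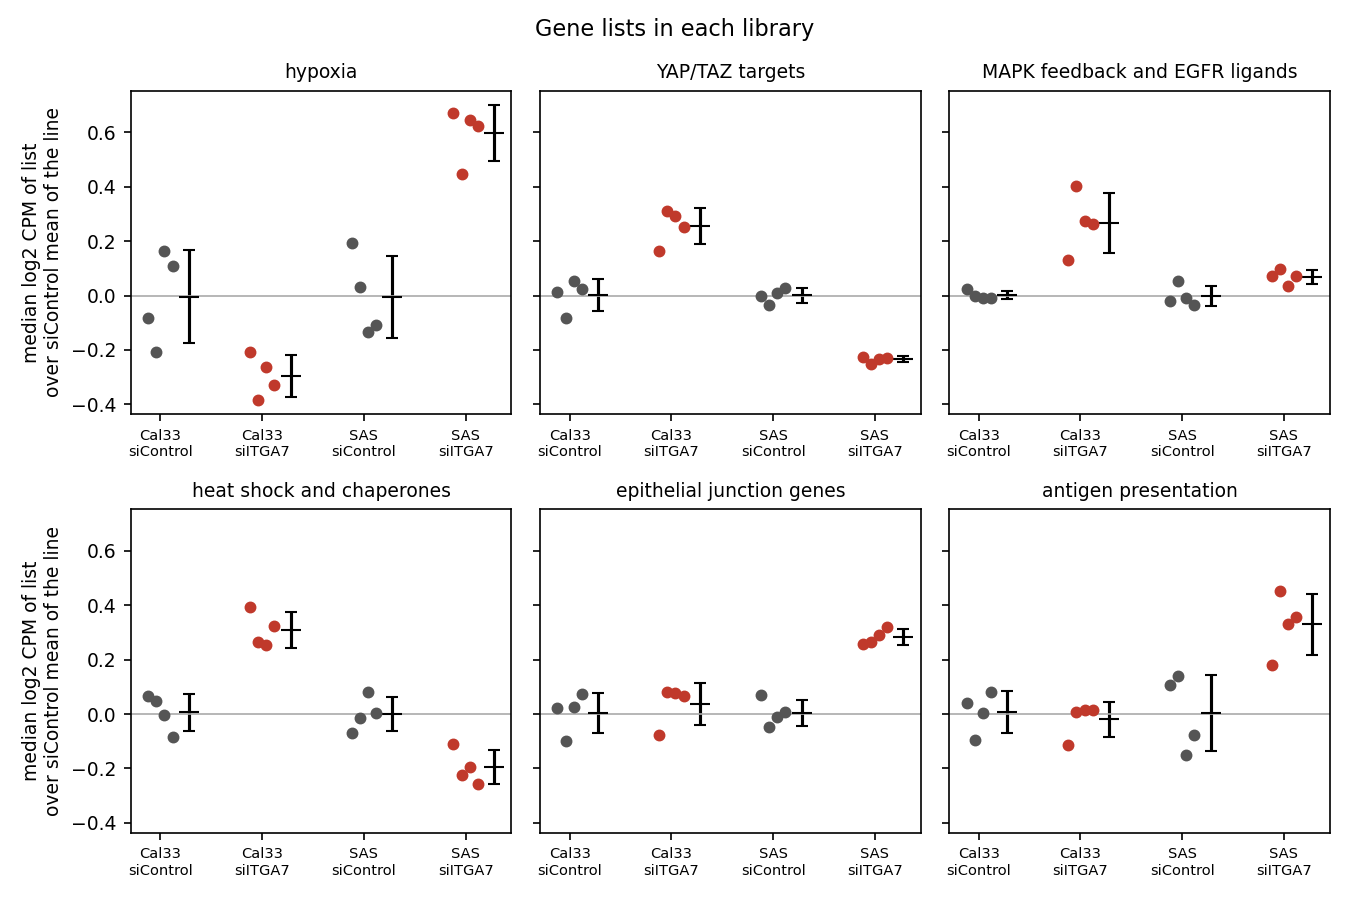
Median log2 CPM of the members of 6 gene lists in each library, as the difference from the siControl mean of the same line (vertical axis), for the 4 groups (points are the 4 libraries, the bar and whiskers are mean and SD). Hypoxia genes lie below siControl in Cal33 siITGA7 and above it in SAS siITGA7, where the median log2 fold changes were -0.33 and 0.56.

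Whether the lines responded differently was tested directly, as the difference between the log2 fold change in SAS and that in Cal33. The difference was largest in size among the named genes for ANGPTL4, which fell in Cal33 (75.5 to 23.5 CPM) and rose in SAS (4.51 to 22.1 CPM), with a difference of 4.00 (SE 0.436, edgeR adjusted p = 1.2e-05). The collagen chain COL6A2 also moved in opposite directions, from 4.02 to 2.22 CPM in Cal33 and from 12.0 to 27.6 CPM in SAS (difference 2.05, SE 0.199), as did the protease inhibitor SERPINB1 (99.8 to 74.1 and 25.3 to 43.8 CPM; difference 1.22, SE 0.133). GBP4 and PTAFR had log2 fold changes of 0.02 and 0.03 in Cal33, and their differences were 2.59 (SE 0.2) and 1.34 (SE 0.141). In the other direction, CCN1 and DKK1, which rose in Cal33, had log2 fold changes of -0.12 and -0.18 in SAS, where CCN1 already stood at 1740 CPM in siControl (differences -1.58, SE 0.114, and -1.66, SE 0.131). The activin antagonist FST and the actin-associated ENC1 rose in Cal33 and fell in SAS (differences -1.83, SE 0.15, and -1.45, SE 0.121), and CREB5 differed by -2.60 (SE 0.226).

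Of the lists, hypoxia had the smallest p for the difference between the lines, with 24 of 30 genes responding higher in SAS and none lower (median difference 0.98, camera adjusted p = 2.38e-28). YAP/TAZ targets responded lower in SAS at 12 of 26 and higher at 2, with CCN2 at -2.68 (SE 0.244; camera adjusted p = 6.67e-10). Heat shock genes responded lower at 14 of 23 with none higher, with CCT5 at -0.95 (SE 0.138) and HSPA4 at -0.78 (SE 0.139; camera adjusted p = 1.98e-09). Mesenchymal and EMT genes responded lower at 7 of 29 and higher at 1, with TGFB2 at -1.18 (SE 0.171) and NT5E at -0.87 (SE 0.145; camera adjusted p = 0.00556). TGFB2 and NT5E are also in the YAP/TAZ list, so the calls of these lists are not independent. MAPK feedback and EGFR ligands responded lower at 12 of 33 and higher at 1, including CCND1 (-1.06, SE 0.108) and DUSP4 (-1.45, SE 0.153; camera adjusted p = 1.53e-06; adjusted p = 0.0572 with an estimated correlation). Epithelial junction genes responded higher at 10 of 37 and lower at 2, with PRSS8 at 2.96 (SE 0.424), a gene at 0.411 CPM in SAS siControl, and CLDN4 at 1.19 (SE 0.198; camera adjusted p = 0.000307; adjusted p = 0.0572 with an estimated correlation). Antigen presentation responded higher at 6 of 22 and lower at 1 (camera adjusted p = 0.000341; adjusted p = 0.121 with an estimated correlation), and glycolysis higher at 7 of 23 and lower at 1, with PFKFB3 at 1.10 (SE 0.156; camera adjusted p = 0.00218; adjusted p = 0.567 with an estimated correlation). PFKFB3 is also in the hypoxia list.

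The other 7 lists called for the difference did not keep their call with an estimated correlation. AP-1 genes responded lower in SAS at 11 of 28 and higher at 1, with SRF at -0.69 and JUN at -0.88 (camera adjusted p = 0.00218; adjusted p = 0.643 with an estimated correlation). NF-kB targets responded lower at 7 of 32 and higher at 1, with CXCL8 at -1.78 and CXCL1 at -1.63 (camera adjusted p = 0.0235; adjusted p = 0.591 with an estimated correlation). The call of NF-kB targets and inflammatory cytokines ended with limma-voom (0.129) and in protein-coding genes (0.0978). Cytosolic ribosomal proteins responded higher at 5 of 52, with RPS20 at 0.35 and RPL15 at 0.61 (camera adjusted p = 0.00218; adjusted p = 0.591 with an estimated correlation). The median difference of these cytosolic ribosomal proteins was 0.16, and 0.10 without replicate 1 of Cal33 siITGA7. The call for RPS20 in interaction with the line ended with the replicate block (edgeR adjusted p = 0.102) and without SAS siControl replicate 4 (0.33, edgeR adjusted p = 0.0522). That for RPL15 in interaction with the line ended without Cal33 siControl replicate 3 (0.59, edgeR adjusted p = 0.0525) or SAS siControl replicate 2 (0.56, edgeR adjusted p = 0.0556).

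Mitochondrially encoded genes were called higher as a list with 0 of 13 members past the edgeR test singly (camera adjusted p = 0.0063; adjusted p = 0.643 with an estimated correlation). In Cal33 siITGA7 their mean over siControl was -1.34 on the log2 scale in replicate 1 and -0.26 to 0.16 in the other 3. Without that library the median difference was 0.46 instead of 0.68 (camera adjusted p = 0.0119). Interferon-stimulated genes (5 of 42 higher, DDX60 at 0.81 and SAMD9L at 1.10), cholesterol synthesis (8 of 33 lower and 2 higher, with STARD4 at 1.26) and small RNA silencing machinery (6 of 13 lower, XPO5 at -0.60 and AGO2 at -0.52) were each called at a camera adjusted p of 0.0484, which became 0.075 with the replicate block. Their adjusted p was 0.315, 0.416 and 0.591 with an estimated correlation. Each of these 3 calls also ended in 9 of the 16 fits that left out 1 library, with the highest camera adjusted p at 0.091 (without SAS siITGA7 replicate 2), 0.0894 (without Cal33 siControl replicate 4) and 0.123 (without Cal33 siITGA7 replicate 1). In protein-coding genes the call of cholesterol and fatty acid synthesis (0.131) and of small RNA silencing machinery (0.128) ended, and so did both with a CPM filter (0.0691). That of interferon-stimulated genes ended with limma-voom (0.0611) and total-count scaling (0.057).

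Adjusted over the list alone, the counts of genes responding higher and lower in SAS were 25 and 1 for hypoxia, 2 and 15 for YAP/TAZ, 0 and 17 for heat shock, 2 and 7 for EMT, 2 and 14 for MAPK feedback, 12 and 2 for epithelial junctions, 8 and 1 for antigen presentation and 7 and 1 for glycolysis. They were 2 and 11 for AP-1, 3 and 8 for NF-kB, 5 and 0 for ribosomal proteins, 0 and 0 for mitochondrially encoded genes, 5 and 0 for interferon-stimulated genes, 2 and 10 for cholesterol synthesis and 1 and 7 for small RNA silencing.

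In total 2935 genes differed in their response between the lines by edgeR's quasi-likelihood test, 1246 higher in SAS and 1689 lower, and the count was 1785 with the replicate block. Of the 40 lists, 15 were called, 7 higher and 8 lower, and 4 held with an estimated correlation (hypoxia, YAP/TAZ, heat shock and EMT).

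The last comparison of the siRNA arms asked which genes moved the same way in both lines. Genes lower in both included NPM3 (log2 fold change -1.29 in Cal33 and -1.58 in SAS), AURKA (-1.10 and -1.55), the acyltransferase LCLAT1 (-1.08 and -1.31), AK4 (-1.17 and -1.05), the calcium-binding CPNE3 (-1.04 and -1.16) and the noncoding RNA LINC02035 (-1.10 and -1.18). Genes higher in both included GOLGA7B (0.95 and 1.07), the myeloid receptor TREM1 (0.91 and 1.17), the adhesion molecule ICAM1 (0.75 and 0.81), the sphingosine-phosphate lyase SGPL1 (0.64 and 0.68), ANKRD10 (0.63 and 0.81) and the signalling kinase IRAK2 (1.17 and 0.62). Counted over all tested genes, 245 were lower in both lines, against 92.4 for independent lists of these sizes, and 130 were higher in both, against 89.1. A further 186 rose in Cal33 and fell in SAS (110.6 for independent lists) and 100 fell in Cal33 and rose in SAS (74.4). Across all tested genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of -0.024. The lines had separate control libraries. When the libraries were split otherwise and lists of the same lengths were taken by p, they shared up to 242 lower genes, up to 237 higher genes and up to 405 in all with the same direction. With the replicate block the number of genes changed in both lines, 375 with the same direction, was 207, and it was 668 without replicate 1 of Cal33 siITGA7. The block gave 148 genes lower in both lines, against 34.3 for independent lists, and 59 higher, against 26.8. With that library left out and the GC trend removed, 542 were lower in both, against 333.

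**Figure D3:**
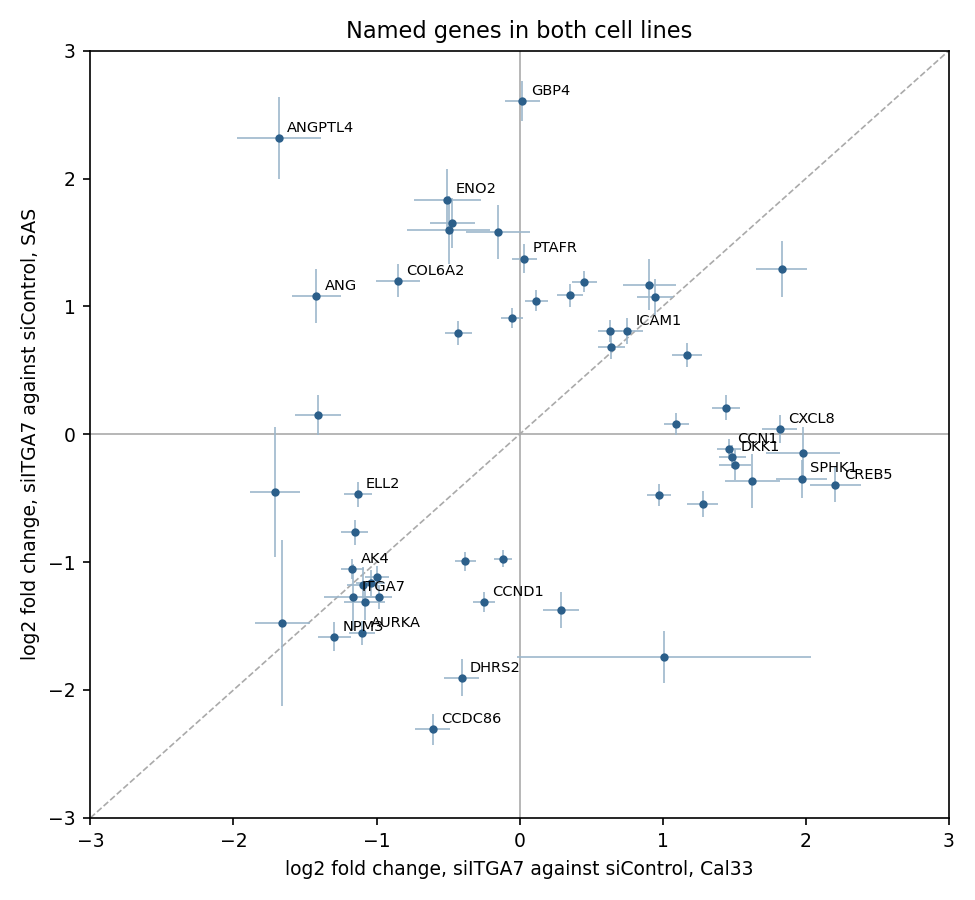
Log2 fold change of siITGA7 against siControl in Cal33 (horizontal axis) and SAS (vertical axis) for the genes named by the fixed rule (points, with SE in both directions); the dashed line marks equal changes. AURKA, NPM3 and AK4 lie near it at the lower left, and ANGPTL4 lies at -1.68 in Cal33 and 2.32 in SAS.

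As background, the lines were compared in siControl. The mucosal keratin KRT13 stood at 6970 ± 797 CPM (SD, n = 4) in Cal33 and 0.439 ± 0.366 CPM (SD, n = 4) in SAS. The atypical cadherin FAT1 had 0 counts in all 4 SAS siControl libraries and 15845 in the 4 Cal33 ones, so it was at least 5200-fold lower in SAS, taking 3 counts over the group as the floor. On the same floor, PCLO was at least 5200-fold and UBQLN2 at least 3041-fold lower in SAS. Conversely the metallothionein MT1E was at least 11034-fold, IL1RAPL1 at least 3452-fold, the phosphatase DUSP2 at least 2487-fold and ZFHX4 at least 2026-fold higher in SAS. TMEM200A had 18088 counts in SAS and 1 in Cal33, a ratio of 18400 with a 95% counting interval of 3300 to 726000.

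Of the lists, SAS was lower in interferon-stimulated genes (35 of 42 lower and 3 higher, camera adjusted p = 3.53e-14), keratinocyte differentiation (29 of 34 lower and 5 higher, 4.07e-09; adjusted p = 0.0509 with an estimated correlation) and epithelial junctions (30 of 37 lower and 4 higher, 1.65e-08). NRF2 genes (24 of 33 lower and 2 higher), antigen presentation (18 of 22 lower and 1 higher) and hypoxia genes (25 of 30 lower and 2 higher) were lower as well, with camera adjusted p of 8.01e-09, 0.000174 and 0.000336, and adjusted p of 0.0509, 0.122 and 0.528 with an estimated correlation. It was higher in NF-kB targets (24 of 32, with 6 lower), YAP/TAZ targets (20 of 26, with 6 lower), mesenchymal and EMT genes (20 of 29, with 7 lower) and MAPK feedback genes (21 of 33, with 9 lower), with camera adjusted p of 4.07e-09, 4e-08, 0.0011 and 7.28e-05. With an estimated correlation the adjusted p was 0.0601 for NF-kB and 0.122 for MAPK feedback. Basal keratinocyte genes (15 of 24 lower and 5 higher, camera adjusted p = 0.000326) and head and neck cancer stem-like markers (7 of 12 lower and 3 higher, camera adjusted p = 0.0491) were also lower in SAS, and G1/S and DNA replication genes (25 of 41 higher and 7 lower, camera adjusted p = 0.00945) and cytosolic ribosomal proteins (44 of 52 higher and 0 lower, camera adjusted p = 7.28e-05) higher. Their adjusted p was 0.0509, 0.168, 0.559 and 0.356 with an estimated correlation. The interferon, epithelial junction, YAP/TAZ and EMT lists held with an estimated correlation. The call of head and neck cancer stem-like markers ended without SAS siControl replicate 1 or 2 (camera adjusted p = 0.0527 and 0.0603), with limma-voom (0.192), with a CPM filter (0.0824), in the 8 siControl libraries alone (0.0688), in protein-coding genes (0.125) and with the GC trend removed (0.0815).

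Adjusted over the list alone, the counts of genes higher and lower in SAS were 3 and 35 for interferon, 5 and 29 for keratinocyte differentiation, 4 and 30 for epithelial junctions, 3 and 25 for NRF2, 1 and 18 for antigen presentation, 2 and 25 for hypoxia, 5 and 15 for basal keratinocyte and 5 and 7 for stem-like genes. They were 24 and 6 for NF-kB, 20 and 6 for YAP/TAZ, 20 and 7 for EMT, 21 and 9 for MAPK feedback, 25 and 7 for G1/S and 44 and 0 for ribosomal protein genes. AP-1 genes were called higher in SAS with the replicate block alone (camera adjusted p = 0.048, against 0.0512 without it; adjusted p = 0.694 with an estimated correlation and no block). In total 16769 of 21086 genes differed by edgeR's quasi-likelihood test, 8435 higher and 8334 lower in SAS. Of the 40 lists, 14 were called, 6 higher and 8 lower.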

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

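The tests of the GC gap, of depth and of a wrong label for 1 library below were chosen after the result was seen; so were the counts of splits per gene list and the ranked lists of fixed length.

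Replicate 1 of Cal33 siITGA7 differed from the other 3 libraries of its group, with which its log2 CPM correlated at 0.975 to 0.976, and mitochondrially encoded genes took 0.98% of its counts and MALAT1 1.63% (0.723% to 0.906% in the others). The 10% of genes highest in GC lay lower in it than the 10% lowest in GC (log2 difference -0.855, against at most 0.614 in size in the other 15 libraries), so GC bias may account for part of its deviation. After the GC trend was removed, the spread of its deviations was 0.367 against at most 0.165 in the others, which argues against GC bias as the whole cause. Depth and a wrong label were argued against: the shallowest library had a spread of 0.126, and ITGA7 in replicate 1 was at 3.03 CPM, below the lowest Cal33 siControl library (4.23 CPM), with 9 of 9 genes named between the lines nearer to Cal33. No biological explanation was tested, and a difference in the handling of this library, whose RNA concentration in the labels was the lowest of the 16 (28.8 ng per µl, against 36.3 to 41.6 in its group), stays open.

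Hypoxia genes were lower in Cal33 and higher in SAS after siITGA7. The direction in Cal33 did not come from replicate 1 of siITGA7 (median -0.297 without it) or from 1 extreme siControl library (the median nearest to 0 with 1 left out was -0.276), and leaving out each of the 16 libraries gave -0.368 to -0.276 in Cal33 and 0.549 to 0.642 in SAS, with camera adjusted p of at most 2.16e-07 and 4.04e-16. With the GC trend removed and the replicate block, the medians differed by 0.913. In siControl the list already stood lower in SAS than in Cal33 (median log2 difference -1.22). The same siControl libraries enter that comparison and the difference of responses, so these results are not independent. The hypothesis that the lines respond differently to ITGA7 silencing is open, and so is a difference in oxygen or cell density between cultures, which was not measured and may set these genes. With an estimated correlation the adjusted p was 0.276 in Cal33, 0.092 in SAS and 0.0353 for the difference, and 4 of 35, 2 of 35 and 1 of 60 splits gave a p as small.

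Other splits of the libraries were refitted. In Cal33 and SAS 1 of 35 splits, the real one, gave as many genes (2334 and 3311, with at most 19 and 0 in the others). The other splits mix siITGA7 with siControl libraries, so a real effect widens their spread and lowers their counts. Among the 8 splits that part all 4 numbered pairs the others gave 0, but 8 splits are too few to exclude chance. Between the lines in siControl 1 of 35 gave as many (16769, others 0) and for the difference 1 of 60 (2935, others at most 652). These splits also mix the groups and were taken without regard to the numbered pairs, so they show only that the real split ranked first. For genes with the same direction in both lines 1 of 60 splits gave as many (375, others 0), which decides nothing, since no other split had a gene called in both lines. With as many genes per line and direction taken by p in every split as the real one calls, chance cannot be excluded for the 375 genes (4 of 60 splits shared as many, another 405). For the 245 genes lower in both lines the real split ranked first (1 of 60), by a narrow margin, since another split shared 242. The 60 splits were drawn without regard to the numbered pairs, so chance is not firmly excluded for these 245 genes. For the 130 genes higher in both, another split shared 237, so chance cannot be excluded. For the number of called lists chance cannot be excluded in Cal33 (12, with 4 of 35 splits as large and another at 14) or SAS (12, with 4 of 35 and another at 16). For the difference (15) 2 of 60 splits, the real one included, called as many. Since the other one called 18, chance is not firmly excluded there. Splits parting all 4 pairs gave up to 12 lists in Cal33 and 15 in SAS. List by list, 1 of 35 splits, the real one, gave a p as small in Cal33 for MAPK feedback, YAP/TAZ, heat shock, matrix proteases and EMT, and in SAS for YAP/TAZ, antigen presentation, epithelial junctions and matrix proteases. The same held in Cal33 for p53 targets and head and neck cancer stem-like markers, which were not called (camera adjusted p = 0.0766 and 0.151). With 40 lists and 35 splits, some first ranks arise by chance. For histones, ribosomal proteins, AP-1 and NRF2 in Cal33, 11, 12, 12 and 10 splits gave a p as small, and for AP-1 and histones in SAS 19 and 12. It was 2 for NF-kB and 4 for cholesterol synthesis and for hypoxia in Cal33. In SAS it was 2 for hypoxia, 4 for glycolysis, heat shock and the unfolded protein response, 5 for interferon-stimulated genes and 6 for laminins. For the difference between the lines, 1 of 60 splits gave a p as small for hypoxia, YAP/TAZ and heat shock, and 2 for MAPK feedback, epithelial junctions and EMT. It was 4 for glycolysis and small RNA silencing, 5 for antigen presentation and cholesterol synthesis, 7 for ribosomal proteins, 15 for AP-1, NF-kB and interferon-stimulated genes, and 25 for mitochondrially encoded genes.

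The effect of siITGA7 differed between the lines by the edgeR test of the difference for 75 of 111 named genes, against 13.9% of all tested genes. Of the 111, 10 were named by the gene rule for this difference. Further ones, such as DUSP4, CXCL1, PRSS8 and HSPA4, were named as list members of smallest p for it. Others were named for a large fold in 1 line, so the share is in large part set by the choice. The log2 fold change in SAS minus that in Cal33 was above 0 for 31: ANGPTL4 4, PRSS8 2.96, GBP4 2.59, ANG 2.5, ENO2 2.34 and VLDLR 2.12. Next came HERC3 2.09, COL6A2 2.05, DEPP1 1.74, EGLN3 1.66, NDRG1 1.62, GPR160 1.56, PTAFR 1.34 and STARD4 1.26. Smaller differences were those of SERPINB1 1.22, CLDN4 1.19, ITGB6 1.15, SAMD9L 1.1, PFKFB3 1.1, MAST4 0.965, ITGA5 0.935, ERAP1 0.93 and DDX60 0.806. Then followed those of B2M 0.75, MTSS1 0.742, PLAU 0.733, ELL2 0.662, CDH1 0.615, RPL15 0.605, LAMC1 0.352 and RPS20 0.347. It was below 0 for 44: CCN2 -2.68, CREB5 -2.6, HSPB8 -2.4, SPHK1 -2.32, RRAD -2.13, KRT86 -2, FST -1.83 and CXCL8 -1.78. Next came KRT80 -1.75, CCDC86 -1.7, DKK1 -1.66, RAP1GAP2 -1.66, CXCL1 -1.63, CCN1 -1.58, DHRS2 -1.5, ENC1 -1.45 and DUSP4 -1.45. Smaller in size were MYL9 -1.32, IFFO2 -1.23, TGFB2 -1.18, CCND1 -1.06, TNFAIP3 -1.02, F3 -1.02, HSPH1 -0.972, ADAMTS1 -0.968, CCT5 -0.95 and JUN -0.877. Then followed NT5E -0.875, VCL -0.859, MAFK -0.843, AJUBA -0.807, DUSP6 -0.79, HSPA4 -0.783, AREG -0.73, SRF -0.694 and KLF6 -0.619. The smallest in size were MFN2 -0.613, SPARC -0.604, XPO5 -0.601, HMGCS1 -0.559, IRAK2 -0.55, H1-1 -0.531, AGO2 -0.522 and AURKA -0.455.

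Single libraries stood apart from the other 3 of their group in 26 of 360 groups of 4 values tested, where chance gives about 5%, or 18. In Cal33 siITGA7 replicate 1 these were SGPL1 at 184 CPM, KLF6 at 185, ITGB1 at 544, CCT5 at 263 and RPL7 at 81.3, above the others, and PTAFR at 72.2, SQLE at 58.6, RPL14 at 61.4 and CXCL1 at 3.77, below them. In the other Cal33 libraries they were CXCL8 at 13.3 and B2M at 535 in siITGA7 replicate 2, UBE2Q2 at 78.1 in siControl replicate 3, FST at 33.3 and H2AC6 at 231 in siControl replicate 1, SQLE at 39.5 in siControl replicate 4 and HSPB8 at 17.1 in siControl replicate 2. In SAS siITGA7 they were CPNE3 at 96.4, DDX60 at 14.4, STAT2 at 31.2, SLC7A5 at 221 and TGFB2 at 37.5 in replicate 1, and GBP4 at 6.88 in replicate 4. In SAS siControl they were HERC3 at 2.39, CCDC86 at 68.4 and DUSP4 at 88 in replicate 1, and ERAP1 at 44.5 in replicate 2.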

How the results depend on the processing

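Removal of the GC trend, alone or without replicate 1 of Cal33 siITGA7, was chosen after the data were seen. The fall of ITGA7 kept its call in both lines under every alternative run, and leaving out 1 library gave log2 fold changes of -1.28 to -1.02 in Cal33 and -1.42 to -1.15 in SAS. The count between the lines in siControl stayed within 1.5 times (16492 to 17733 with 1 library left out). Each of the following settings moved at least 1 count by more, and the cause was not tested unless named. With the replicate block within each line, which pairs libraries by the number in the labels, the counts were 1214 in Cal33, 2128 in SAS and 1785 for the difference, of which 1207, 2116 and 1764 were also called without it. For genes changed in both lines the block gave 207. Apart from the calls given beside their results, the block changed no call of a list or named gene. Against a fold of 1.2, a stricter test by construction, the counts were 471, 1068 and 1339. With the GC trend removed they were 3592, 5004 and 4495, and 711 for genes changed in both lines. With replicate 1 of Cal33 siITGA7 left out as well they were 4043, 6956, 5691 and 978. The 8 Cal33 libraries alone gave 1316, while the 8 SAS libraries alone gave 4623, within 1.5 times the count of 3311. Leaving out 1 library gave 1305 to 3376 in Cal33, with 1553 and 1305 without siControl replicates 2 and 3. It gave 2331 to 5236 in SAS and 268 to 668 in both lines. For the difference it gave 2100 to 4340, within 1.5 times the count of 2935. These ranges were each highest without replicate 1 of Cal33 siITGA7. With an estimated correlation 4 lists were called in Cal33, 2 in SAS and 4 for the difference. With each of the 16 libraries left out in turn, 8 of the 12 called lists kept their call every time in Cal33, 11 of 12 in SAS, 12 of 15 for the difference and 13 of 14 between the lines. Over all settings, 151 values of named genes and list members lost their call in 44 cases, 15 of them against a fold of 1.2, gained it in 9 (RPL7 and MT-ND5) and stayed on their side of the threshold in 4580. None reversed. ITGA7 in SAS rests on 13 to 63 counts per library, so depth limits the precision of its fold.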

Other observations

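The tests of 1 left-out library and of the GC trend below, the shares of genes with sites, the matching on UTR length and the ranked split were chosen after the result was seen.

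More long noncoding RNAs rose than fell in SAS: of 3631 tested, 214 rose and 58 fell. Of 13738 protein-coding genes 1139 rose and 1640 fell. In Cal33, 77 long noncoding RNAs rose and 76 fell, against 1058 and 908 protein-coding genes. Small RNA silencing genes fell at 6 of 13 and rose at 1 in SAS, without a call for the list (camera adjusted p = 0.12; adjusted p = 0.628 with an estimated correlation). Fibrillar and matricellular matrix genes rose at 4 of 24 and fell at 7 in Cal33, where the list was not called (camera adjusted p = 0.976) and its median of -0.12 and mean of -0.04 lay on the other side of 0 from its test. In SAS they rose at 7 and fell at 2 (camera adjusted p = 0.128).

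The most abundant markers of other cell types in Cal33 siControl were COL1A1 at 13.8 ± 1.23 CPM among fibroblast, VWF at 15.6 ± 1.10 CPM among endothelial, CSF1R at 6.23 ± 1.09 CPM among leukocyte and TNNT1 at 22.8 ± 2.38 CPM among skeletal muscle genes (SD, n = 4 each). In SAS siControl they stood at 1.52 ± 0.477, 2.17 ± 0.588, 3.04 ± 0.283 and 11.9 ± 2.53 CPM (SD, n = 4 each). The leukocyte and muscle lists, with 5 measured genes each, were not called in Cal33 (camera adjusted p = 0.894 and 0.976) or SAS (1 and 0.975), and their medians, means and tests differed in sign in both lines except for muscle genes in Cal33.

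The 245 genes lower in both lines, against 92.4 for independent lists and 242 shared by rank in another split of the libraries, were searched for 7-base words in the 3′ UTR, since siRNAs may lower other transcripts through seed matches. Of 16205 words, 3 (GCTCAGA, GCTGCTT and GCTACTT) went with lower fold changes in both lines (regression, Benjamini-Hochberg adjusted p of at most 0.000288 in Cal33 and 0.000933 in SAS), 0 with higher ones, and all 3 occur in ITGA7 transcripts, as 21.3% of the words do. Counted per line, 4 words went with lower and 5 with higher fold changes in Cal33, and 8 and 0 in SAS. The regression t values of all words had a correlation of -0.0694 between the lines. The log2 effects of the 3 words called in both lines were small: -0.076, -0.0479 and -0.0585 in Cal33, and -0.0895, -0.0715 and -0.0637 in SAS. At least 1 of these 3 words was in 75.1% of 229 searched genes lower in both lines, in 31.3% of all 13383, and in at most 52.8% in 10000 sets matched on UTR length, but the words were picked from the same fold changes. The count lower in both lines was 2.65 times the independent count, and 1.94 times without replicate 1 of Cal33 siITGA7. It was 1.92 times with the GC trend removed, 1.63 without both, and 4.32 with the replicate block alone. Genes that moved in opposite directions also exceeded the independent count (186 against 110.6 and 100 against 74.4 over all tested genes). These ratios can therefore not be read against 1. They do not decide whether that library or the GC trend accounts for the excess. Whether seeds do cannot be told either. The ratio was 1.4 among 9199 genes with none of the words (57 against 40.6), 2.11 among those with 1 or more and 2.14 over all searched genes. Each independent count used the share of calls among its own genes, which takes up any surplus of lower genes among those with words. The comparison of these ratios therefore decides nothing about seeds. Genes higher in both lines, which seeds of the ITGA7 pool would not raise, stood at 1.21, 1.76 and 1.35 times. Seed matching is a hypothesis, since the siRNA sequences were not used here, and loss of ITGA7 stays open as a cause. This holds also for AURKA, NPM3, LCLAT1, AK4, CPNE3, CCDC86, CCND1, ELL2, MAT2B, MFN2 and UBE2Q2, lower in both lines, which carry such words. PRPS2 and DHRS2, lower in both, carry none. Of genes named as higher in both lines, ANKRD10 and SGPL1 carry such words, while GOLGA7B, TREM1, ICAM1 and IRAK2 carry none.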
